A study of Homo sapiens with 16 samples.

How the data were processed

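RNA was sequenced from the cytoplasmic and nuclear fractions of 2 human liver cancer cell lines, HepG2 and SNU-449, 48 h after transfection with a negative control siRNA (NC) or with a mixture of siPANAD-1 and siPANAD-2, both aimed at PANAD (gene symbol C7orf25). Each combination of line, fraction and siRNA had 2 libraries, which the series' design text calls biological duplicates, so there were 8 groups and 16 libraries. Groups and replicate numbers were taken from the sample labels.

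The deposited values were raw read counts per gene, in 1 table per cell line, with versioned Ensembl gene identifiers. Per the submitters' processing notes, the tools were Trim Galore 0.6.4 and HISAT2 2.2.1 with the hg38 genome; the program that counted the reads, the annotation release and the strand setting were not given in the sources used here. The libraries were directional per the labels' protocols. Because the use of strand in counting was not stated, reads of a gene and of an antisense partner may not have been told apart, and genes that overlap another gene are named as such where they occur. The counts were used as deposited, with no rounding. Of the 67938 gene identifiers in each table, 61444 matched a symbol table, and the unmatched ones held 0.0306% (HepG2) and 0.0414% (SNU-449) of all counts. The entry of 1 gene, ANK2, was broken over several lines in both tables and was left out. All 15 mitochondrially encoded genes had 0 counts in every library, so they were not tested and could not serve as a measure of mitochondrial carry-over. Symbols, positions and overlaps between genes came from GENCODE release 29 on GRCh38.

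Total counts per library ran from 16238235 to 30321908. The HepG2 cytoplasm NC replicate 2 library held the highest number, and the next highest was 19498081. A gene with 0 counts in a library could have been present at up to 3 counts, which corresponds to 0.099 to 0.185 CPM (counts scaled to the library total). Such limits and the intervals on count ratios (exact, 95%) cover counting error only, since PCR copies were not separable from original molecules. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom between 4.09 and 29.9, the highest in the HepG2 cytoplasm NC pair, and their log2 CPM correlated across genes with Pearson coefficients of 0.982 to 0.992.

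Differential expression was computed in R 4.3.3 with edgeR 4.0.16. In each line the 8 libraries were fitted together with 1 mean per group, since 2 libraries per group leave few degrees of freedom on their own. Genes were kept by filterByExpr (minimum count of 10), libraries were scaled by the TMM method, and contrasts were tested with glmQLFit (robust) and glmQLFTest, the quasi-likelihood (QL) F-test. The filter kept 17499 genes in HepG2 and 17895 in SNU-449, and the common biological coefficient of variation was 0.101 and 0.0728. Tests were two-sided. The threshold was an adjusted p under 0.05 by the Benjamini-Hochberg (BH) method across all genes tested in a contrast, and adjusted p-values in the text come from this test unless another is named. In each line 4 contrasts were tested: siPANAD against NC in the cytoplasm, the same in the nucleus, nucleus against cytoplasm in NC, and the difference of the first 2 (nuclear minus cytoplasmic log2 fold change), called the shift of the nucleus to cytoplasm ratio. TMM sets the middle of the genes of each library to the same level, so a change shared by nearly all genes of a fraction is not visible, and a nucleus to cytoplasm ratio is relative to the typical gene, not an amount per cell. Differences between the lines were tested in 1 fit of all 16 libraries (20459 genes), as the SNU-449 effect minus the HepG2 effect. Levels are given as TMM-normalised CPM, mean ± SD of 2 libraries, and effects as log2 fold changes with their standard error (SE).

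Before the data were examined, 24 gene lists were fixed: cytosolic ribosomal proteins, snoRNA host genes, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, MYC and ribosome biogenesis, cholesterol biosynthesis, the unfolded protein response and ATF4, hypoxia and glycolysis, immediate-early genes, YAP/TEAD targets, p53 targets, apoptosis regulators, interferon response, replication-dependent histones, DNA replication, G1 cyclins and their kinases, G2/M and mitosis, mRNA export factors, the nuclear pore complex, the spliceosome with SR and hnRNP proteins, nuclear-retained lncRNAs, hepatocyte markers (for HepG2), mesenchymal markers (for SNU-449), and immune and blood cell markers. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with BH adjustment over the lists of a contrast, and again with an estimated correlation. Members past the threshold were counted with the adjusted p over all genes and adjusted over the list alone.

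The genes named were also fixed by rule: C7orf25, CDK6 and NXF1 always; in each knockdown contrast and ratio shift the 8 largest rises and 8 largest falls among genes with a symbol, a mean of at least 2 on the log2 CPM scale, an adjusted p under 0.05 and both siPANAD libraries on the same side of both NC libraries; up to 4 members per list with the smallest p; 5 genes on each side of the NC nucleus against cytoplasm contrast; the 5 smallest p-values of each line difference; and, for genes called in both lines, 6 per direction with the largest smaller change. Not every gene the rule allowed is named, and the results of some are not reported here.

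The same code was tested on simulated counts drawn with the means, library sizes and spread of the real libraries. In the line difference, the SNU-449 cytoplasm with siPANAD was instead drawn with a fixed spread. Per line only 67, 67 and 66 genes, none at very low levels, were changed 1.5-, 2- and 4-fold, in the cytoplasm alone. In addition 1 gene list was moved. Far more genes were called in the data, so these rates need not hold there. In the HepG2 cytoplasm it recovered 46.3% of genes changed 1.5-fold, 86.6% of genes changed 2-fold and 92.4% of genes changed 4-fold (16573 genes run), and for the ratio shift 11.9%, 73.1% and 86.4%. In SNU-449 these shares were 52.2%, 77.6% and 98.5% in the cytoplasm and 31.3%, 67.2% and 97.0% for the ratio shift (17138 genes run). Between 0 and 14 unchanged genes were called in a contrast. In the line difference of the cytoplasm, 51.9% of the 185 genes made to differ were recovered.

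All alternatives were fixed beforehand. They were RLE size factors, no filter on low counts, a stricter filter (CPM of at least 1) and DESeq2 1.42.0 (Wald test). Replicate number was used as a block, over all groups or nested in treatment. Each library was left out in turn, and the libraries of 1 fraction were fitted alone. A trend on the nucleus to cytoplasm ratio of the other line was removed from every library, as a stand-in for differences in fraction purity. Lists were also tested by camera with an estimated correlation and by fry. Calls shared by the lines were also counted at a looser threshold of 0.1. For the closing section, the longest annotated 3' UTR of each gene was searched for all 16384 7-base words, and each word's presence was regressed on the changes, with 3' UTR length and GC content as covariates and changes limited to ±2 log2 units. In 20 simulated draws per line, with the changes shuffled over genes, a word given an effect of 0.2 ranked first every time. Shuffling removes any link between the base composition of 3' UTRs and the changes. These draws therefore do not show how specific a high-ranking word is in the data. The word reported beside the leading one (the highest in SNU-449 that does not overlap it) was settled on after the results of the word scan had been seen.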

Results

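Cytoplasmic and nuclear RNA was sequenced from HepG2, a hepatoblastoma-derived liver cell line with many hepatocyte traits, and SNU-449, a hepatocellular carcinoma line with mesenchymal traits. Cells had been transfected for 48 h with a control siRNA (NC) or with 2 siRNAs against PANAD, a protein encoded by C7orf25 (siPANAD). There were 2 biological replicates of each line, fraction and siRNA, 16 libraries in all, with 16238235 to 30321908 counts each. The series title links PANAD to the mRNA export receptor NXF1, to the export of CDK6 mRNA and to the G1/S transition. The comparisons asked how the cytoplasmic and nuclear levels of mRNAs, and the ratio between them, changed with siPANAD. By MALAT1, a long non-coding RNA held in the nucleus, the cytoplasmic libraries held little nuclear RNA. It was at 2.21 to 5.84 CPM in the cytoplasmic and 370 to 634 CPM in the nuclear libraries, before TMM scaling. On the same scale NEAT1, another nuclear RNA, was at 62.2 and 89.6 CPM in HepG2 cytoplasm NC and 1168 and 1344 in HepG2 nucleus NC. GAPDH mRNA, also before scaling, was at 4045 to 5934 CPM in the cytoplasmic and 884 to 1365 CPM in the nuclear libraries. In HepG2 the cytoplasm had 5518 and 4302 in NC and 5013 and 5934 with siPANAD, the nucleus 1113 and 996, and 884 and 1045. In SNU-449 the cytoplasm had 4361 and 4045 in NC and 5340 and 5155 with siPANAD, the nucleus 1252 and 1365, and 1334 and 1279. How much of the nuclear GAPDH mRNA was carried over from the cytoplasm is not known.

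The targeted gene, C7orf25 (ENSG00000136197, chromosome 7, 42908726 to 42912305, minus strand, GRCh38), was near 0 in every library and could not be used to check the knockdown. In the HepG2 cytoplasm it had 0 and 1 counts in the NC replicates and 0 and 0 with siPANAD. In the HepG2 nucleus it had 0 and 2 counts in NC and 1 and 4 with siPANAD. In SNU-449 the cytoplasm had 3 and 2 counts in NC and 0 and 0 with siPANAD, and the nucleus 5 and 7 in NC and 3 and 4 with siPANAD. The SNU-449 cytoplasm gave the tightest limit, a siPANAD to NC ratio of at most 1.15 (exact 95% interval of the pooled counts), which does not exclude an unchanged level. In the SNU-449 nucleus the ratio was 0.602, with an interval of 0.201 to 1.66. Of the exonic bases of C7orf25, 61.2% are shared on the same strand with other annotated genes. Among them is ENSG00000256646 (42909273 to 42932174), which spans C7orf25 and the adjacent proteasome subunit gene PSMA2 and had a mean of 0.562 counts per library. PSMA2 itself (42916857 to 42932223) had a mean of 32.6 counts per library. MRPL32, whose start lies beside that of PSMA2 on the other strand, had 1156.

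**Figure D1:**
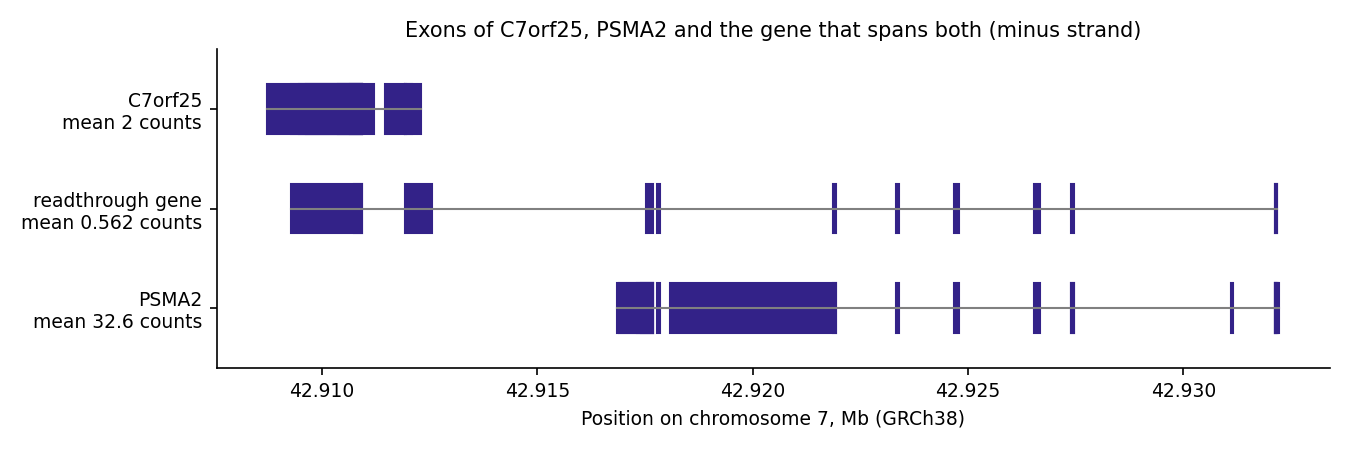
Exons (boxes) of C7orf25, of the readthrough gene that spans both, and of PSMA2, all on the minus strand, against position on chromosome 7 in Mb (GRCh38), with the mean counts per library beside each name. C7orf25 (mean of 2 counts) shares 61.2% of its exonic bases with other genes on its strand, PSMA2 (32.6) shares 14.64%, and the readthrough gene (0.562) shares 90.19%. Shares are of the bases of all annotated exons, which in PSMA2 include a long one (42918074 to 42921931).

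CDK6, the cyclin-dependent kinase that acts in G1 (ENSG00000105810, chromosome 7, 92604921 to 92836594, minus strand), was lower with siPANAD in both fractions of both lines, and more so in the cytoplasm. In the HepG2 cytoplasm it went from 116 ± 4.10 CPM (SD, n = 2) in NC to 35.6 ± 0.721 with siPANAD, a 3.27-fold fall (log2 fold change -1.71, SE 0.13; edgeR QL test, BH-adjusted p = 3.8e-11). In the HepG2 nucleus it went from 70.9 ± 3.17 to 48.2 ± 1.87 CPM, a 1.47-fold fall (-0.56, SE 0.12; edgeR adjusted p = 5.2e-04). The fall in SNU-449 was 5.41-fold in the cytoplasm, from 199.6 ± 2.56 to 36.9 ± 2.58 CPM (-2.43, SE 0.10; edgeR adjusted p = 2.4e-20). It was 1.74-fold in the nucleus, from 109.6 ± 0.676 to 62.8 ± 5.57 CPM (-0.80, SE 0.09; edgeR adjusted p = 9.6e-09). The nucleus to cytoplasm ratio of CDK6 therefore rose 2.22-fold in HepG2 (log2 1.15, SE 0.17; edgeR adjusted p = 1.3e-04) and 3.10-fold in SNU-449 (log2 1.63, SE 0.14; edgeR adjusted p = 1.5e-10). Tested directly, the cytoplasmic fall was deeper in SNU-449 than in HepG2 by -0.77 (SE 0.16; edgeR adjusted p = 4.5e-04). The nuclear falls (-0.26; adjusted p = 0.263) and the ratio shifts (0.50; adjusted p = 0.385) were not called different by the same edgeR test.

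NXF1, the receptor that carries bulk mRNA through the nuclear pore (ENSG00000162231, chromosome 11, 62792123 to 62806302), was called lower in the nucleus of both lines, but the calls depended on single libraries. It went from 201.5 ± 3.23 to 160.6 ± 17 CPM in HepG2 (-0.33, SE 0.12; edgeR adjusted p = 0.034) and from 113.8 ± 19.7 to 94.0 ± 2.47 CPM in SNU-449 (-0.28, SE 0.10; edgeR adjusted p = 0.023). In SNU-449 the value was -0.10 without nucleus NC replicate 2 (99.8 and 127.7 CPM in the NC replicates) and -0.45 without nucleus NC replicate 1. The SNU-449 call was lost without nucleus NC replicate 2 and without nucleus siPANAD replicate 1 (-0.31) or 2 (-0.25). The HepG2 call was lost without nucleus NC replicate 1 (-0.33), nucleus siPANAD replicate 1 (-0.22) or cytoplasm siPANAD replicate 1 or 2 (-0.29 each). It was also lost with no filter on low counts in HepG2 (-0.30) and with DESeq2 in SNU-449 (-0.27), where removal of the purity trend gave -0.48. In the cytoplasm it did not pass the test in HepG2 (-0.19; edgeR adjusted p = 0.247) or SNU-449 (0.05; adjusted p = 0.793, and -0.05 with the purity trend removed). Its nucleus to cytoplasm ratio did not pass the edgeR test in either line (-0.14 and -0.33; adjusted p = 0.709 and 0.160), except in SNU-449 without nucleus NC replicate 1 (-0.50) and with the purity trend removed (-0.43).

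**Figure D2:**
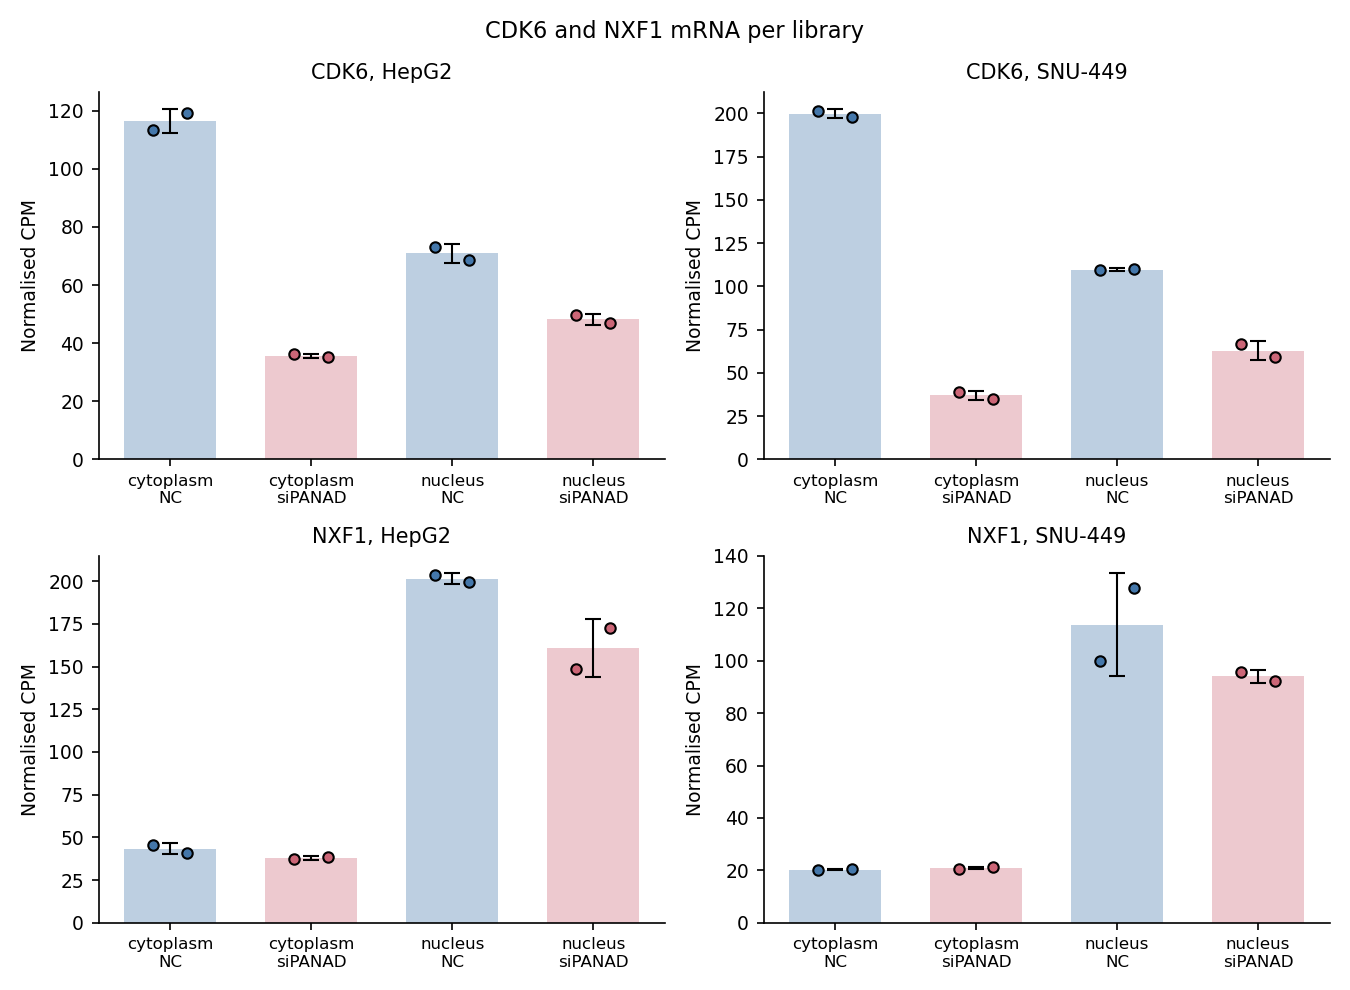
TMM-normalised CPM of CDK6 and NXF1 in each library (points) with the group mean (bar) and SD (error bar, n = 2), for NC and siPANAD in the cytoplasm and nucleus of HepG2 and SNU-449. CDK6 in the cytoplasm went from 116 to 35.6 CPM in HepG2 and from 199.6 to 36.9 CPM in SNU-449, with smaller falls in the nucleus.

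In the HepG2 cytoplasm IGFBP1, an insulin-like growth factor binding protein secreted by liver cells, fell 18.9-fold, from 3558 ± 108 to 188 ± 47.0 CPM (log2 fold change -4.24, SE 0.21, n = 2 per group). INHBB, an activin subunit (-3.62, SE 0.17), CEMIP, which takes part in hyaluronan breakdown (-3.52, SE 0.14), the hyaluronan synthase HAS3 (-3.40, SE 0.23) and the growth factor receptor PDGFRB (-3.37, SE 0.23) fell in the same fraction. The largest rises started from low levels. AMHR2, the anti-Müllerian hormone receptor, went from 0.274 ± 0.183 to 20.9 ± 2.25 CPM. PRR15L went from 0.754 ± 0.248 to 42.0 ± 1.09 CPM, and GNMT, a methyltransferase of the liver, from 1.99 ± 0.248 to 35.2 ± 1.19 CPM (4.16, SE 0.19).

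In total 8390 of the 17499 genes tested changed in the HepG2 cytoplasm at an adjusted p under 0.05 by edgeR's QL test, 4149 higher and 4241 lower with siPANAD.

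Of the 78 cytosolic ribosomal protein genes 66 rose in the HepG2 cytoplasm, 0 fell and 12 did not pass the test (66 rose and 1 fell adjusted over the list alone). RPL29 (1.23, SE 0.15) and RPL11 (1.24, SE 0.15) were among them. Their median log2 fold change was 0.92 (camera adjusted p = 4.0e-18, but adjusted p = 0.197 with an estimated correlation). The same genes took up 11.7% and 11.8% of all counts in the NC replicates and 20.2% and 20.02% with siPANAD. Of 24 cholesterol synthesis genes 21 rose, 2 fell and 1 did not pass, with a median of 0.98 (camera adjusted p = 1.2e-07, adjusted p = 0.197 with an estimated correlation). FDFT1, the squalene synthase (1.98, SE 0.14), and MSMO1 (2.09, SE 0.16) were among those that rose. In the interferon list 24 of 41 genes rose, 0 fell and 17 did not pass (camera adjusted p = 3.4e-07, adjusted p = 0.0723 with an estimated correlation). IFIT3 (2.85, SE 0.19) and IFIT1 (2.71, SE 0.23) were members that rose. For p53 targets, 20 of 32 rose, 3 fell and 9 did not pass (camera adjusted p = 4.3e-05, adjusted p = 0.0723 with an estimated correlation). DDB2, a DNA damage recognition factor, rose (2.08, SE 0.13) and GDF15, a stress-induced secreted factor, fell (-2.01, SE 0.17).

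Oxidative phosphorylation genes, with 32 of 65 higher, 3 lower and 30 not past the threshold, had a median of 0.42 (camera adjusted p = 2.1e-04, adjusted p = 0.511 with an estimated correlation). NDUFB1, a subunit of complex I, was among those that rose (2.18, SE 0.16). Histone genes also rose as a list, 8 of 24 with 1 lower and 15 not past the threshold (camera adjusted p = 0.00465, adjusted p = 0.197 with an estimated correlation).

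In the HepG2 cytoplasm immediate-early genes fell in 25 of 30 cases, with 1 higher and 4 not past the threshold, and a median of -1.25 (camera adjusted p = 6.9e-16, adjusted p = 0.0723 with an estimated correlation). The transcription factor EGR1 (-2.95, SE 0.16) and TRIB1 (-2.69, SE 0.14) were examples. MYC and ribosome biogenesis genes fell in 29 of 38 cases, with 1 higher and 8 not past the threshold (30 lower adjusted over the list alone). Their median was -0.72 (camera adjusted p = 1.3e-08, adjusted p = 0.0723 with an estimated correlation), and MYC itself fell (-1.53, SE 0.15). The unfolded protein response list fell in 27 of 36, with 1 higher and 8 not past the threshold (camera adjusted p = 5.4e-09, adjusted p = 0.0723 with an estimated correlation). The chaperone HSPA5 (-1.77, SE 0.13) and TRIB3 (-2.26, SE 0.15) fell in it. Hypoxia and glycolysis genes were lower in 17 of 34 cases and higher in 5 (camera adjusted p = 1.7e-05, adjusted p = 0.197 with an estimated correlation). The glucose transporter SLC2A3 (-3.31, SE 0.14) and hexokinase HK2 (-2.26, SE 0.14) fell.

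The mesenchymal list (12 lower and 3 higher of 23, and 13 lower adjusted over the list alone) had a camera adjusted p of 4.4e-05, and adjusted p = 0.197 with an estimated correlation. YAP/TEAD targets (10 lower and 6 higher of 20), CCN2 at -2.18 (SE 0.14) among them, had a camera adjusted p of 9.0e-04, and adjusted p = 0.0723 with an estimated correlation. Nuclear pore genes fell in 19 of 34 cases with 0 higher and 15 not past the threshold (camera adjusted p = 0.00465, adjusted p = 0.197 with an estimated correlation), among them POM121 (-1.02, SE 0.14). Here and in the other comparisons, counts adjusted over the list alone were the same as over all genes where no second count is given. The 10 tested lists that camera did not call in the HepG2 cytoplasm had adjusted p between 0.0741 and 0.808. They were apoptosis regulators (10 higher, 14 lower of 34), DNA replication (16 and 11 of 50), G1 cyclins (6 and 13 of 30), G2/M (1 and 17 of 49, and 1 and 15 adjusted over the list alone), and hepatocyte markers (17 and 10 of 36). The others were immune and blood cell markers (4 and 2 of 11), mRNA export factors (7 and 15 of 42, and 7 and 16 adjusted over the list alone), lncRNAs (3 and 4 of 16), snoRNA hosts (8 and 3 of 23) and the spliceosome (11 and 19 of 58). The median of the 36 hepatocyte markers was 0.34, and that of the 19 also tested in SNU-449 was -0.21.

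In the HepG2 nucleus IGFBP1 was again among the deepest falls, from 1532 ± 200 to 61.0 ± 16.7 CPM (-4.65, SE 0.21, n = 2 per group). AKAP12, a scaffold of protein kinase A (-3.38, SE 0.14), the collagen cross-linking enzyme LOX (-3.35, SE 0.16) and the growth factor AREG (-3.32, SE 0.15) fell as well. TRIM50 rose from 16.5 ± 1.81 to 279 ± 5.23 CPM (4.08, SE 0.14). NEAT1, the RNA scaffold of paraspeckles, rose by 1.13 (SE 0.15). It was at 1168 and 1344 CPM before scaling in the NC libraries and at 3274 and 2875 with siPANAD. By edgeR's QL test 7981 of 17499 genes changed, 3843 higher and 4138 lower.

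All 38 genes of the MYC and ribosome biogenesis list fell in the HepG2 nucleus, with a median of -0.82 (camera adjusted p = 9.8e-16, and adjusted p = 0.0251 with an estimated correlation, so the call was kept). The nucleolar proteins GNL3 (-1.44, SE 0.13) and DKC1 (-1.45, SE 0.13) were examples. Cholesterol synthesis rose in 22 of 24 genes and fell in 2 (camera adjusted p = 3.9e-15, adjusted p = 0.105 with an estimated correlation). HMGCS1 (2.42, SE 0.16) and LSS (2.14, SE 0.13) rose. G2/M genes fell in 32 of 49 cases, with 0 higher and 17 not past the threshold (36 lower adjusted over the list alone). Their median was -0.45 (camera adjusted p = 1.5e-05, adjusted p = 0.241 with an estimated correlation), and CENPF, a kinetochore protein, fell (-1.54, SE 0.14). Interferon genes rose (21 higher and 1 lower of 41, and 22 and 1 adjusted over the list alone; camera adjusted p = 2.1e-06, adjusted p = 0.0516 with an estimated correlation). So did p53 targets (21 higher and 2 lower of 32, and 22 and 2 adjusted over the list alone; camera adjusted p = 2.1e-07, adjusted p = 0.0516 with an estimated correlation).

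Immediate-early genes fell in the HepG2 nucleus too (22 lower and 3 higher of 30, and 22 and 4 adjusted over the list alone; camera adjusted p = 1.1e-11, adjusted p = 0.105 with an estimated correlation). The unfolded protein response fell (26 lower and 1 higher of 36; camera adjusted p = 6.7e-10, adjusted p = 0.0516 with an estimated correlation). Camera also called hypoxia genes (18 lower and 4 higher of 34; adjusted p = 4.8e-07), mesenchymal markers (14 and 4 of 23; 2.9e-07), nuclear pore genes (18 and 1 of 34; 9.4e-04) and YAP/TEAD targets (10 and 6 of 20; 0.0342). These calls were lost with an estimated correlation, at camera adjusted p = 0.151 for hypoxia and 0.150 for the other lists. Adjusted over the list alone, 21 hypoxia genes, 21 nuclear pore genes and 11 YAP/TEAD targets were lower. Ribosomal protein genes had no camera call (5 higher and 4 lower of 78, and 0 and 2 adjusted over the list alone; adjusted p = 0.846), nor did oxidative phosphorylation (6 and 6 of 65, and 1 and 2 adjusted over the list alone; 0.724). The difference from the cytoplasm is tested by the ratio shift. The export factors (2 higher and 14 lower of 42, and 1 and 12 adjusted over the list alone; camera adjusted p = 0.0739) and spliceosome genes (6 and 18 of 58; 0.0902) were not called. The other 8 tested lists of the HepG2 nucleus had camera adjusted p between 0.204 and 0.891. Median and mean of the immune markers differed in sign in the HepG2 nucleus (-0.04 and 0.03). The medians of G1 cyclins (-0.04) and hepatocyte markers (0.09) were 0.03 and -0.20 in the 27 and 19 members also tested in SNU-449.

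In the SNU-449 cytoplasm COL4A1, a basement membrane collagen, fell from 179 ± 6.40 to 15.4 ± 1.09 CPM (-3.54, SE 0.11, n = 2 per group). COL1A1, the main chain of fibrillar collagen, fell from 88.6 ± 2.95 to 8.87 ± 1.02 CPM (-3.32, SE 0.12). GINS2, part of the replicative helicase, fell from 105 ± 2.21 to 14.1 ± 0.373 CPM (-2.89, SE 0.12), and the cytokine IL11 from 32.7 ± 0.532 to 4.60 ± 0.376 CPM (-2.83, SE 0.15). LY6K fell by 3.29 (SE 0.14), but 71% of its exonic bases lie opposite another gene. UHMK1, a kinase that binds RNA-processing factors, rose from 20.1 ± 2.52 to 184 ± 30.7 CPM (3.20, SE 0.12; edgeR adjusted p = 8.6e-20). DENND6A rose from 9.84 ± 0.222 to 67.3 ± 11 CPM (2.77, SE 0.13). By edgeR's QL test 7106 of 17895 genes changed, 3515 higher and 3591 lower.

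Mesenchymal markers fell in 26 of 38 cases in the SNU-449 cytoplasm, with 4 higher and 8 not past the threshold, and a median of -0.73 (camera adjusted p = 1.5e-17). COL6A3 was among those that fell (-2.05, SE 0.10). The unfolded protein response fell in 26 of 36 cases, with 2 higher (camera adjusted p = 3.4e-11). Both calls were kept with an estimated correlation, at camera adjusted p = 0.0106 and 0.0275. In the latter list TRIB3 fell (-1.91, SE 0.10) and CANX, a chaperone of glycoprotein folding, rose (1.35, SE 0.09). YAP/TEAD targets fell (14 lower and 4 higher of 25; camera adjusted p = 4.3e-06, adjusted p = 0.0575 with an estimated correlation), CCN1 (-1.59, SE 0.10) among them. Hypoxia genes fell as well (11 lower and 3 higher of 31; camera adjusted p = 2.5e-04, adjusted p = 0.0577 with an estimated correlation). Immediate-early genes were 16 lower and 5 higher of 33, and 18 and 6 adjusted over the list alone (camera adjusted p = 2.5e-04, adjusted p = 0.395 with an estimated correlation). Apoptosis regulators were 18 lower and 7 higher of 33, and 19 and 7 adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.105 with an estimated correlation).

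G1 cyclins and their kinases fell in 11 of 28 cases with 4 higher (12 lower adjusted over the list alone; camera adjusted p = 0.0232, adjusted p = 0.128 with an estimated correlation). CDK6 and CCNE1, the cyclin E1 gene (-0.85, SE 0.10), fell, while E2F5 rose (1.23, SE 0.13). Cholesterol synthesis genes were 4 higher and 10 lower of 25 in the SNU-449 cytoplasm, with a median of -0.06 (camera adjusted p = 0.0308, adjusted p = 0.139 with an estimated correlation). The difference from HepG2 was not tested for lists. Host genes of snoRNAs rose in 15 of 24 cases with 0 lower (16 adjusted over the list alone; camera adjusted p = 2.1e-06, adjusted p = 0.0577 with an estimated correlation), for example SNHG3 (1.66, SE 0.12). Ribosomal protein genes rose in 34 of 78 cases, with 2 lower and 42 not past the threshold (36 higher adjusted over the list alone). Their median was 0.26 (camera adjusted p = 1.8e-05, adjusted p = 0.485 with an estimated correlation). Their share of all counts was 11.3% and 11.5% in NC and 14.3% and 14.6% with siPANAD.

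Oxidative phosphorylation genes also rose in the SNU-449 cytoplasm (29 higher and 3 lower of 65; camera adjusted p = 0.00192, adjusted p = 0.508 with an estimated correlation). Histone genes rose (17 higher and 0 lower of 43, and 18 adjusted over the list alone; camera adjusted p = 0.00192, adjusted p = 0.0577 with an estimated correlation). The 10 tested lists that camera did not call there had adjusted p from 0.0731 to 0.676. They were G2/M (3 higher and 17 lower of 49), MYC and ribosome biogenesis (4 and 15 of 38, and 4 and 16 adjusted over the list alone), DNA replication (11 and 20 of 50), interferon (14 and 3 of 37, and 15 and 4 adjusted over the list alone) and export factors (4 and 12 of 43). The others were the nuclear pore (2 and 9 of 34), lncRNAs (3 and 0 of 17), the spliceosome (18 and 15 of 58), p53 targets (10 and 9 of 30, and 11 and 10 adjusted over the list alone) and hepatocyte markers (4 and 6 of 20). Of the immune markers 2 were measured in SNU-449 and both rose, too few for a list test. Medians and means differed in sign for hepatocyte markers (-0.25 and 0.07) and p53 targets (-0.06 and 0.01, direction up by camera). The median of the spliceosome genes (0.00) turned to -0.03 with the purity trend removed, and that of the lncRNAs (0.07, and 0.02 in the 14 members also tested in HepG2) to -0.03 in those 14.

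In the SNU-449 nucleus PERP, a membrane protein of cell junctions, fell from 163 ± 27.6 to 23.3 ± 2.06 CPM (-2.81, SE 0.14, n = 2 per group) and GREM1, a secreted antagonist of BMP, from 46.6 ± 3.91 to 8.96 ± 1.60 CPM (-2.38, SE 0.13). TMEM187 rose from 5.76 ± 0.680 to 33.0 ± 0.672 CPM (2.52, SE 0.13), and TXNIP, a thioredoxin-interacting protein induced by glucose, from 2.82 ± 0.402 to 14.1 ± 1.77 CPM (2.32, SE 0.18). NEAT1 rose by 2.18 (SE 0.10; edgeR adjusted p = 4.8e-19), from 547 and 563 CPM before scaling in NC to 2526 and 2682 CPM with siPANAD. MALAT1 rose by 0.53 (SE 0.09). By edgeR's QL test 8232 of 17895 genes changed, 3951 higher and 4281 lower.

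Genes of G2/M and mitosis fell in 39 of 49 cases in the SNU-449 nucleus, with 0 higher and 10 not past the threshold (41 lower adjusted over the list alone), and a median of -0.45 (camera adjusted p = 2.8e-10, adjusted p = 0.147 with an estimated correlation). CENPF (-1.33, SE 0.10) and the mitotic kinesin KIF20A (-1.04, SE 0.10) were examples. DNA replication genes fell in 28 of 50 cases with 5 higher (30 lower adjusted over the list alone; camera adjusted p = 4.4e-04, adjusted p = 0.190 with an estimated correlation). GINS2 (-2.11, SE 0.12), the thymidine kinase TK1 (-0.89, SE 0.09) and RRM2 (-0.85, SE 0.09) fell. Mesenchymal markers fell (22 lower and 2 higher of 38, and 23 lower adjusted over the list alone; camera adjusted p = 3.4e-07, adjusted p = 0.0540 with an estimated correlation), with COL4A1 at -2.09 (SE 0.09). The unfolded protein response fell too (25 lower and 3 higher of 36, and 4 higher adjusted over the list alone; camera adjusted p = 1.0e-07, adjusted p = 0.0540 with an estimated correlation), with HSPA5 at -1.01 (SE 0.09). Hypoxia genes were lower (11 lower and 3 higher of 31, with camera adjusted p = 0.0179, and adjusted p = 0.147 with an estimated correlation). Their median of -0.15 went to -0.03 with the purity trend removed. Histone genes rose (11 higher and 0 lower of 43, and 10 adjusted over the list alone; camera adjusted p = 0.0240, adjusted p = 0.147 with an estimated correlation).

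G1 cyclins (2 higher and 13 lower of 28; camera adjusted p = 0.0586), YAP/TEAD targets (5 and 13 of 25; 0.0586) and export factors (5 and 18 of 43; 0.0789) were not called by camera in the SNU-449 nucleus. The other 13 tested lists had camera adjusted p between 0.117 and 0.849. Ribosomal protein genes (4 higher and 17 lower of 78, and 4 and 15 adjusted over the list alone), oxidative phosphorylation (4 and 17 of 65, and 2 and 14 adjusted over the list alone) and cholesterol synthesis (2 and 6 of 25, and 2 and 5 adjusted over the list alone) were among these. Their medians of -0.08, -0.13 and -0.09 (-0.07 in the 24 cholesterol genes also tested in HepG2) turned to 0.16, 0.02 and 0.03 with the purity trend removed. Apoptosis regulators had a median of 0.04 and a mean of -0.03.

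**Figure D3:**
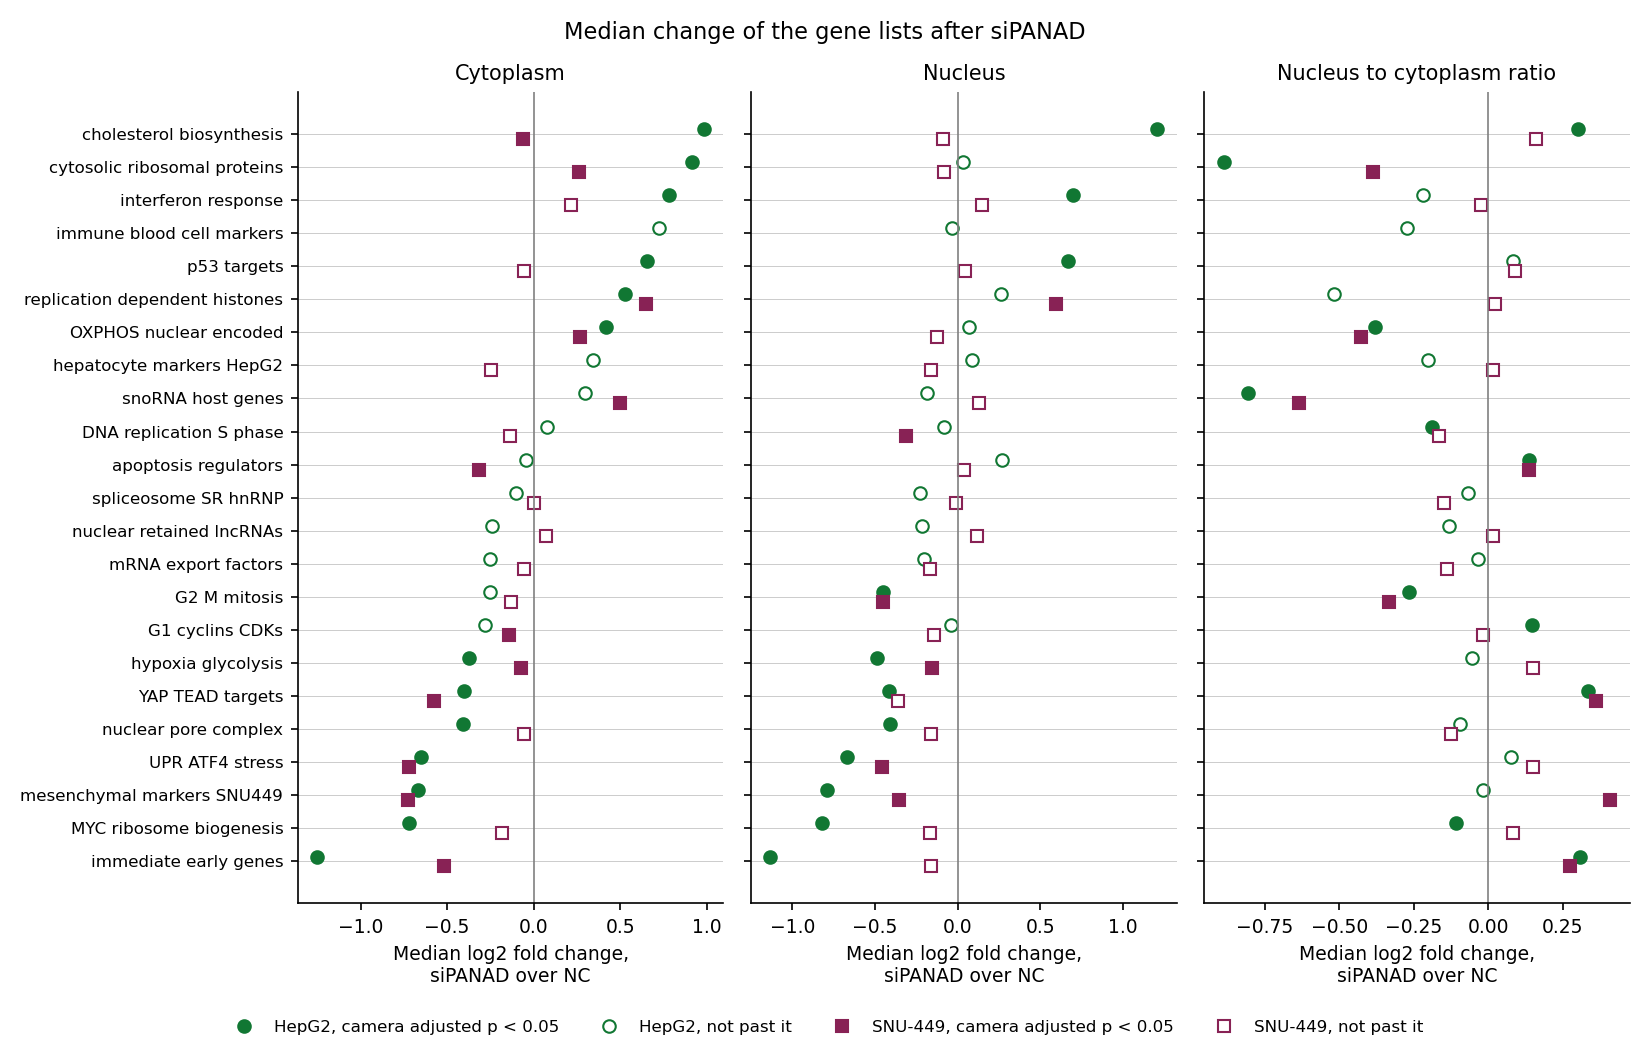
Median log2 change (siPANAD over NC, horizontal axis) of each gene list in the cytoplasm, in the nucleus and in the nucleus to cytoplasm ratio, for HepG2 (circles) and SNU-449 (squares), filled where camera's adjusted p at the preset correlation was under 0.05. Cytosolic ribosomal protein genes sit at 0.92 in the HepG2 and 0.26 in the SNU-449 cytoplasm, and at 0.03 and -0.08 in the nuclei, the last turning to 0.16 with the purity trend removed.

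The shift of the nucleus to cytoplasm ratio asked which mRNAs changed differently in the 2 fractions, the question raised by an export factor. In HepG2 the ratio rose for the signalling protein SHH (2.19 on the log2 scale, SE 0.27, n = 2 per group), for cyclin D2, encoded by CCND2 (2.11, SE 0.36), and for ZFTA (1.90, SE 0.20). It fell for RBM7, a factor of nuclear RNA decay (-1.99, SE 0.25), and for NDUFB1 (-1.80, SE 0.21). RBM7 went from 6.51 ± 0.298 to 32.9 ± 1.02 CPM in the cytoplasm, with 3.80 ± 0.191 and 4.83 ± 0.410 CPM in the nucleus. By edgeR's QL test 1730 of 17499 genes shifted, 859 upward and 871 downward. Leaving out 1 siPANAD library changed this number by more than 1.5 times: it was 1010 and 1077 without cytoplasm replicates 1 and 2, and 1057 and 841 without nucleus replicates 1 and 2. With no filter on low counts 68.2% of the called shifts were upward, against 49.7% with it.

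The ratio fell for ribosomal protein genes in HepG2, 57 of 78 with 0 the other way and 21 not past the threshold (63 adjusted over the list alone). Their median was -0.89 (camera adjusted p = 7.4e-45, adjusted p = 0.351 with an estimated correlation), and -0.78 with the purity trend removed. The other lists called in the HepG2 shift all had an adjusted p of 0.418 by camera with an estimated correlation. Among these, host genes of snoRNAs (9 down and 2 up of 23, and 11 down adjusted over the list alone; camera adjusted p = 1.2e-06) went down, GAS5 (-1.30, SE 0.20) included. Oxidative phosphorylation (14 down and 1 up of 65, and 18 down adjusted over the list alone; camera adjusted p = 8.2e-07) also did, with UQCRB at -0.99 (SE 0.19). So did G2/M (2 down and 0 up of 49, and 0 and 0 adjusted over the list alone; 0.00317), MYC and ribosome biogenesis (4 down and 0 up of 38, and 6 down adjusted over the list alone; 0.0170) and DNA replication (4 down and 1 up of 50; 0.0339), by camera adjusted p. Apoptosis regulators (7 up and 0 down of 34, and 10 up adjusted over the list alone; camera adjusted p = 8.0e-04), cholesterol synthesis (7 up and 1 down of 24, and 9 and 2 adjusted over the list alone; 8.0e-04), and immediate-early genes (4 up and 0 down of 30, and 5 up adjusted over the list alone; 0.00210) went up. So did YAP/TEAD targets (2 up and 0 down of 20, and 4 up adjusted over the list alone; 0.0206) and G1 cyclins (4 up and 0 down of 30, and 7 up and 1 down adjusted over the list alone; 0.0342), by camera adjusted p. TNFRSF10B, a death receptor, shifted by 1.44 (SE 0.18), and RBL2, an RB family protein of G1, by 1.35 (SE 0.21). The other 12 tested lists were not called, export factors among them (5 up and 3 down of 42, and 6 up adjusted over the list alone; camera adjusted p = 0.896). In that list GLE1, a factor of the cytoplasmic side of the pore, was at 1.02 (SE 0.19). Mesenchymal markers had a median of -0.02 and a mean of 0.06 in this contrast, and a median of 0.01 with the purity trend removed. The same removal took the median of the DNA replication genes from -0.19 to -0.11.

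In SNU-449, CCDC43 (2.01, SE 0.25, n = 2 per group) and DNAJC9, a histone chaperone (1.97, SE 0.20), shifted upward, but 19% and 29% of their exonic bases lie opposite another gene. UHMK1 had the clearest downward shift (-2.58, SE 0.16), followed by DENND6A (-1.97, SE 0.18), TRUB1 (-1.90, SE 0.20) and the transcriptional co-activator YAP1 (-1.83, SE 0.15). YAP1 went from 20.4 ± 1.15 to 90.4 ± 11.7 CPM in the cytoplasm and from 44.6 ± 2.07 to 55.4 ± 0.891 CPM in the nucleus. By edgeR's QL test 3614 of 17895 genes shifted, 1734 upward and 1880 downward, and 2392 without nucleus siPANAD replicate 2.

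The ratio rose for mesenchymal markers in SNU-449, 16 of 38 with 3 the other way (19 and 5 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 1.1e-07, adjusted p = 0.0590 with an estimated correlation). COL4A1 (1.45, SE 0.14) and COL6A3 (1.36, SE 0.13) were examples. The list fell in the nucleus too (median -0.35), but less than in the cytoplasm (-0.73). YAP/TEAD targets shifted up (10 up and 3 down of 25, and 13 up adjusted over the list alone; camera adjusted p = 6.8e-04, adjusted p = 0.138 with an estimated correlation). So did immediate-early genes (8 up and 2 down of 33; camera adjusted p = 6.8e-04, adjusted p = 0.540 with an estimated correlation). Apoptosis regulators were 13 up and 5 down of 33, and 14 up adjusted over the list alone (camera adjusted p = 0.00598, adjusted p = 0.138 with an estimated correlation). Ribosomal protein genes (30 down and 2 up of 78, and 42 and 3 adjusted over the list alone) had a median of -0.39 (camera adjusted p = 2.7e-09, adjusted p = 0.520 with an estimated correlation). With the purity trend removed their median was -0.11, and that of oxidative phosphorylation went from -0.43 to -0.27. Oxidative phosphorylation shifted down (28 down and 3 up of 65, and 32 down adjusted over the list alone; camera adjusted p = 8.9e-08, adjusted p = 0.476 with an estimated correlation). G2/M genes were 17 down and 0 up of 49, and 18 down adjusted over the list alone (camera adjusted p = 8.0e-06, adjusted p = 0.281 with an estimated correlation). The snoRNA hosts were 12 down and 2 up of 24 (camera adjusted p = 1.0e-04, adjusted p = 0.138 with an estimated correlation). The other 14 tested lists were not called, with camera adjusted p from 0.110 to 0.825, export factors (6 up and 5 down of 43) among them. Median and mean differed in sign for G1 cyclins (-0.02 and 0.06; in the 27 members also tested in HepG2 the median of -0.04 turned to 0.11 with the purity trend removed), hepatocyte markers (0.02 and -0.10) and interferon genes (-0.02 and 0.11).

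**Figure D4:**
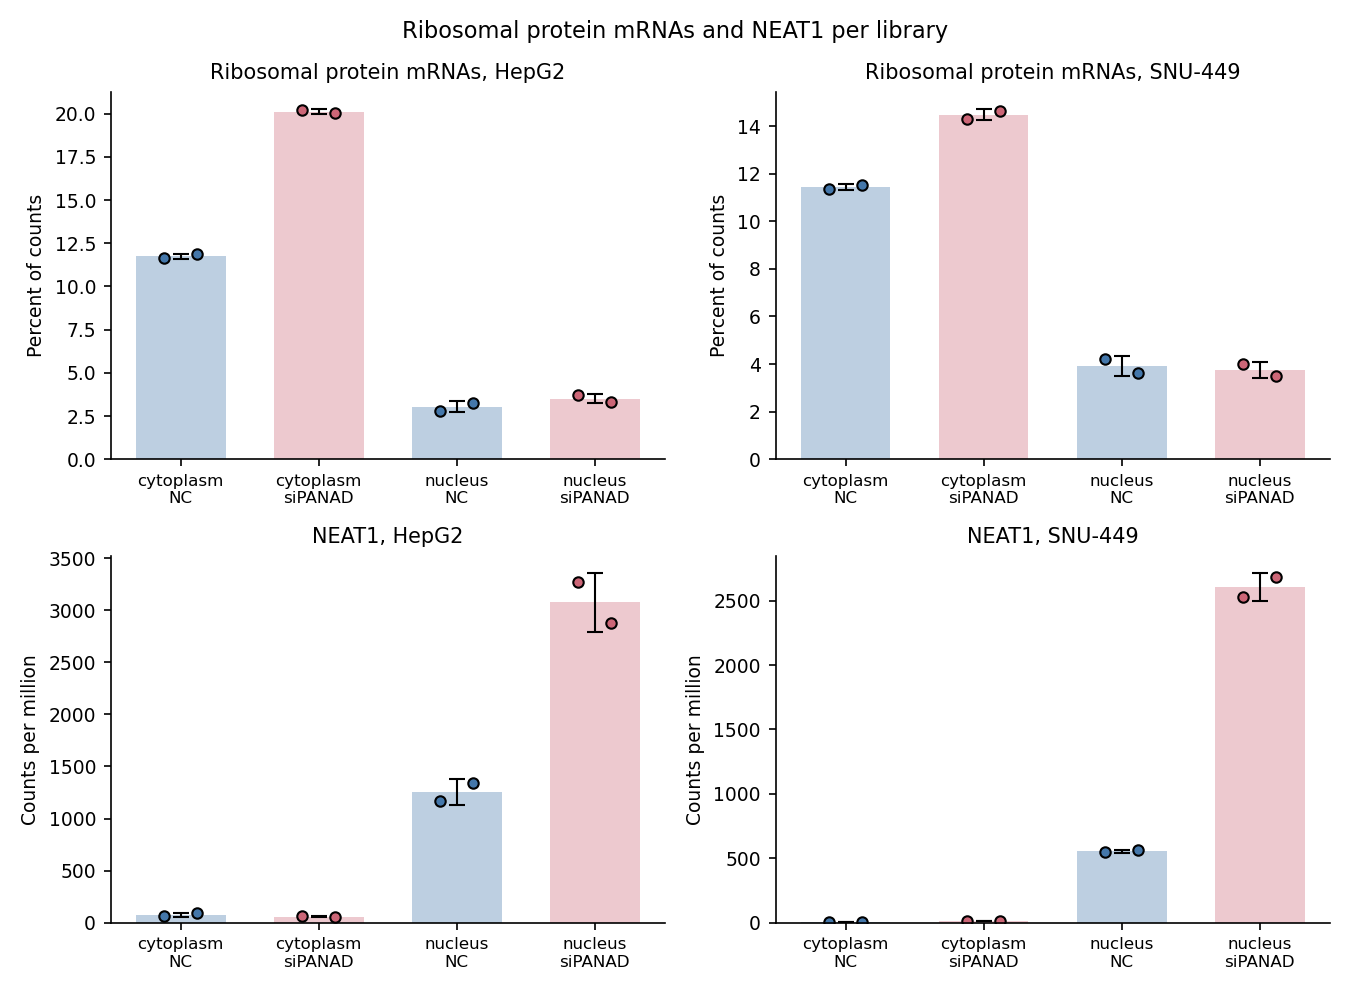
Percent of all counts in the 78 cytosolic ribosomal protein genes and CPM of NEAT1 before scaling in each of the 16 libraries (points), with the group mean (bar) and SD (error bar, n = 2). The ribosomal protein share of the cytoplasm was 11.7% and 11.8% in HepG2 NC against 20.2% and 20.02% with siPANAD, and nuclear NEAT1 in SNU-449 was 547 and 563 CPM in NC against 2526 and 2682 CPM with siPANAD.

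The nucleus against cytoplasm comparison in NC described where each RNA lay without knockdown. MALAT1 was higher in the nucleus of HepG2 by 5.48 (log2, SE 0.15, n = 2 per group), at 312 ± 6.74 against 6.97 ± 0.251 CPM. UBB, a ubiquitin gene with 28% of its exonic bases opposite another gene, was higher in the cytoplasm, at 902 ± 5.25 against 61.7 ± 4.17 CPM (-3.87, SE 0.15). In SNU-449 the GTPase gene RAB32 (-4.95, SE 0.11) and UBB (-4.23, SE 0.11) were higher in the cytoplasm. CRYGS, MIR222HG and GNRH1 had 11.2, 18.4 and 11.4 CPM in the nucleus and stayed at or under the level that 0 counts allow in the cytoplasm. Nuclear-retained lncRNAs were higher in the nucleus in 12 of 16 cases with 0 lower in HepG2 (camera adjusted p = 1.0e-08, adjusted p = 0.224 with an estimated correlation). They were higher in 15 of 17 with 1 lower in SNU-449 (camera adjusted p = 1.2e-10, adjusted p = 0.136 with an estimated correlation). Ribosomal protein genes were lower in the nucleus in 76 of 78 cases in HepG2 (camera adjusted p = 3.2e-33, adjusted p = 0.224 with an estimated correlation). In SNU-449 this held for 72 of 78 (camera adjusted p = 7.2e-23, adjusted p = 0.203 with an estimated correlation). By edgeR's QL test 13492 of 17499 genes differed between the fractions in HepG2 (6892 higher in the nucleus, 6600 lower), and 14272 of 17895 in SNU-449 (7789 and 6483). Interferon genes differed in sign between median and mean in HepG2 (-0.19 and 0.11) and SNU-449 (-0.28 and 0.10), as did immune markers in HepG2 (-0.01 and 0.08, and a median of 0.08 with RLE size factors). The mesenchymal list of HepG2 had a median of 0.11 while camera gave the direction as down. Camera called none of these lists (adjusted p from 0.316 to 0.658).

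Genes that responded in both lines were more numerous than independent lists would share. In the cytoplasm 1641 genes were higher in both lines, against 726 expected from the numbers called among the 15017 genes tested in both, and 1905 were lower, against 830 expected. The nucleus had 1520 shared rises (703 expected) and 1728 shared falls (917 expected). For the ratio shift 450 genes rose in both lines (88.9 expected) and 369 fell in both (94.9 expected), while 8 went opposite ways (184 expected). The lines shared no library. Log2 fold changes correlated across genes, which are not independent replicates, with Pearson coefficients of 0.37 in the cytoplasm, 0.43 in the nucleus and 0.28 for the shift (Spearman 0.47, 0.43 and 0.41). Within a line, cytoplasmic and nuclear changes, which also shared no library, correlated at 0.64 in HepG2 and 0.46 in SNU-449 (Pearson).

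Among shared cytoplasmic changes, UHMK1 rose by 2.53 (SE 0.15) in HepG2 and 3.20 (SE 0.12) in SNU-449, and PIK3IP1, an inhibitor of PI3-kinase, by 2.41 (SE 0.16) and 2.13 (SE 0.19). IL11 fell by 2.90 (SE 0.17) and 2.83 (SE 0.15). PERP changed by -2.32 (SE 0.13) and -2.71 (SE 0.14), and GANAB, the glucosidase II subunit of the endoplasmic reticulum, by -2.22 (SE 0.14) and -2.44 (SE 0.10). In the nucleus PIK3IP1 (2.42 and 2.32), TMEM187 (2.08 and 2.52) and the synaptic vesicle protein gene SYP (2.68 and 2.04) rose in both lines, and PERP (-2.64 and -2.81), PEG10 (-1.78 and -1.80) and METRNL (-2.20 and -1.73) fell. Shared upward shifts of the ratio included MOB3C (1.70 and 1.83), NHLRC3 (1.54 and 1.74), the Mediator subunit MED24 (1.53 and 1.73), the sheddase ADAM17 (1.61 and 1.53) and the palmitoyltransferase ZDHHC18 (1.56 and 1.49). Shared downward shifts included RBM7 (-1.99 and -1.69), the mitotic kinase NEK7 (-1.44 and -1.42) and the histone-binding protein RBBP4 (-1.29 and -1.28).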

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

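No test in this part was chosen after its result was seen: the differences between the lines come from a contrast fixed beforehand, the SNU-449 effect of siPANAD minus the HepG2 effect in 1 edgeR fit of all 16 libraries. The results stand here because the effect of siPANAD differed between the lines by that test. In the cytoplasm 3714 of 20459 genes differed at an adjusted p under 0.05 by edgeR's QL test, 1876 with a higher and 1838 with a lower log2 fold change in SNU-449. This balance depended on the processing: 2133 were higher and 1446 lower with no filter on low counts, but 1723 and 1999 with RLE size factors. ETNK2, an ethanolamine kinase, rose in HepG2 (2.16) and fell in SNU-449 (-0.63), a difference of -2.83 (SE 0.16; edgeR adjusted p = 1.7e-17). SDCBP2 differed by -3.68 (3.18 in HepG2, -0.47 in SNU-449) and LAMA3, a laminin chain, by -3.75 (2.76 and -0.95). The collagen receptor subunit ITGA2 fell further in HepG2, with a difference of 2.66 (-3.16 and -0.46). The receptor tyrosine kinase EPHA2 fell in HepG2 and rose in SNU-449, with a difference of 2.44 (-2.10 and 0.38). For CDK6 the cytoplasmic difference was -0.77, since the fall was deeper in SNU-449.

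In the nucleus 4279 genes differed, 2312 with a higher and 1967 with a lower log2 fold change in SNU-449. EDN1, the endothelin 1 gene, differed by 2.87 (-2.14 in HepG2, 0.75 in SNU-449). ETNK2 differed by -3.12 (2.34 and -0.77) and SDCBP2 by -3.85 (2.86 and -0.97). BMF, a cell death factor, differed by -2.38, with a rise in HepG2 (2.202) and no call in SNU-449 (-0.17).

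For the ratio shift 99 genes differed between the lines by edgeR's QL test, 71 with a higher and 28 with a lower shift in SNU-449. The direction depended on the filter: with no filter on low counts 206 genes differed, 76 higher and 130 lower. DESeq2 gave 241, 176 higher and 65 lower. RPL10A, a ribosomal protein gene, differed by 1.70, with a fall in HepG2 (-1.33) and no call in SNU-449 (0.34). UTP14A, a factor of ribosome biogenesis, differed by 1.59 (-1.44 and 0.12), and CCDC57 by the same amount, 1.59 (-1.30 and 0.26). CALCOCO1 differed by 1.54 (0.12 and 1.63) and NUMBL by 1.97 (-0.74 and 1.20). The number 99 depended on single libraries: it moved by more than 1.5 times when any 1 of 11 libraries was left out, down to 29 without HepG2 cytoplasm siPANAD replicate 2 and up to 483 (246 higher and 237 lower) without HepG2 cytoplasm NC replicate 1. The part on processing names all 11.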

How the results depend on the processing

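All alternatives in this part were fixed beforehand, and none was added after a result was seen. The numbers of knockdown genes, of genes that differed between the fractions in NC, and of genes whose cytoplasmic or nuclear effect differed between the lines stayed within 1.5 times under every alternative run. Their ranges with 1 library left out were 6522 to 8502 (HepG2 cytoplasm), 5723 to 8936 (HepG2 nucleus), 5467 to 7331 (SNU-449 cytoplasm), 5811 to 8453 (SNU-449 nucleus), 12822 to 13750 and 13439 to 14701 (HepG2 and SNU-449 NC), and 2779 to 3950 and 3113 to 4815 (line differences of the cytoplasm and nucleus). In these fits the lone library left in a group is assumed to vary like the other groups. The CDK6 ratio shift kept its call in 15 of 15 alternatives in each line, at 1.10 to 1.26 in HepG2 and 1.53 to 1.72 in SNU-449, with an adjusted p of at most 0.00128 and 9.7e-09 (edgeR, or DESeq2 for that alternative).

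The ratio shift of HepG2 (1730 genes) ranged from 841 to 2346 with 1 library left out. It fell by more than 1.5 times without cytoplasm siPANAD replicate 1 (1010) or 2 (1077) and without nucleus siPANAD replicate 1 (1057) or 2 (841). The shift of SNU-449 (3614) ranged from 2392 to 3650 and moved by more than 1.5 times without nucleus siPANAD replicate 2 (2392). The line difference of the shift (99) was 206 with no filter on low counts, 36.9% of them higher against 71.7%, and 241 with DESeq2. It ranged from 29 to 483: 483 without HepG2 cytoplasm NC replicate 1, 177 without replicate 2 of that group, 64 and 29 without HepG2 cytoplasm siPANAD replicates 1 and 2, 197 without HepG2 nucleus NC replicate 2 and 52 without HepG2 nucleus siPANAD replicate 1. In SNU-449 it was 47 and 43 without replicate 2 of cytoplasm NC and of cytoplasm siPANAD, 65 without nucleus NC replicate 1, and 61 and 38 without nucleus siPANAD replicates 1 and 2. With no filter 68.2% of the HepG2 shifts were upward, against 49.7%, and the median shift of all genes moved by 0.112. With the stricter filter the HepG2 median of nucleus against cytoplasm in NC moved by 0.111. The fit with the purity trend removed covers the 15017 genes tested in both lines. The cause of these changes was not tested.

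NXF1 changed sign in values that were not called: from 0.05 to -0.053 in the SNU-449 cytoplasm with the purity trend removed, and in the nuclear line difference (0.04), which ranged from -0.12 to 0.21 with 1 library left out and was -0.07 without HepG2 nucleus siPANAD replicate 1 and -0.12 without SNU-449 nucleus NC replicate 1. Of the 6680 values of named genes with 1 library left out, 6517 kept their direction and side of the threshold, 160 lost their call, 1 gained one and 2 changed sign. Of the named values, 12 of 812 lost their call with DESeq2, 9 of 814 with no filter, 5 of 814 with the replicate block and 6 of 531 with the purity trend removed. With RLE size factors (814), the stricter filter (807) and a fit of 1 fraction (412), all kept direction and side. Genes called in both lines numbered 4190 (cytoplasm), 3915 (nucleus) and 1250 (shift) at an adjusted p under 0.1 in each line, against 3546, 3248 and 819 at 0.05. Camera with an estimated correlation called at most 2 lists in any of these 6 comparisons, against 13, 11 and 11 in the HepG2 cytoplasm, nucleus and shift and 12, 6 and 8 in SNU-449 at the preset correlation. Fry, which asks only whether a list's genes move one way, called 18, 14 and 3 in HepG2 and 15, 15 and 7 in SNU-449.

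Deviations of same-numbered libraries from their group means correlated only weakly between groups, from -0.078 to 0.073. Whether same-numbered fractions of a treatment came from 1 culture is not settled by this. With such fractions taken as 1 culture, 2141 genes shifted in HepG2 and 3556 in SNU-449, against 1730 and 3614 in the main fit. With the replicate number as a block, 8193, 7684 and 1569 genes were called in the HepG2 cytoplasm, nucleus and shift, and 6988, 8073 and 3525 in SNU-449. The line differences were 3507, 4067 and 81. C7orf25 did not pass the filter on low counts, so its alternatives gave no value except with no filter, where its adjusted p by edgeR's QL test was between 0.0974 (SNU-449 cytoplasm) and 0.893 (HepG2 shift). At the depth of these libraries, 0 counts allow a level of up to 0.099 to 0.185 CPM. With 2 libraries per group, an outlier test and a count of other splits of the samples were not run.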

Other observations

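The tests of words in 3' UTRs, of rises without a word, of nuclear CDK6, of other genes with as many words and of proteasome subunits were chosen only after the results they bear on had been seen, as were the bound for fraction purity and its comparison on the same genes, though the trend removal was itself fixed beforehand, while the tests of coding sequence and of overlapping genes were set before.

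Several export factors changed although their list was not called by camera in any knockdown contrast. Members of the list were called about as often as all tested genes, and some rose. More of the called members fell than rose in each knockdown contrast, while 48.0% to 49.5% of all called genes rose. Of all tested genes, 47.9% in HepG2 and 39.7% in SNU-449 were called in the cytoplasm, and 45.6% and 46.0% in the nucleus. The genes named below were picked from the list and do not show a change of export factors as a group. DDX19A, a helicase that releases mRNA at the cytoplasmic side of the pore, fell in the cytoplasm of HepG2 (-1.74, SE 0.15) and SNU-449 (-1.55, SE 0.12) and in the nucleus (-0.99, SE 0.14, and -0.98, SE 0.11). About 23.8% of its exonic bases are shared with another gene on its strand. The mRNA of NXT1, the partner of NXF1, fell in the cytoplasm of both lines (-0.86, SE 0.13, and -0.61, SE 0.09). For GLE1, which activates DDX19 helicases, the nucleus to cytoplasm ratio rose in HepG2 (1.02, SE 0.19) and SNU-449 (1.32, SE 0.17). It fell in the cytoplasm (-0.79 and -1.09), with no call in the nucleus (0.23 and 0.23).

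In NC cells, genes of 1 process lay in different fractions. In SNU-449 spliceosome genes were higher in the nucleus in 33 of 58 cases and lower in 18 (camera adjusted p = 0.00433, adjusted p = 0.136 with an estimated correlation), with LUC7L3 at 3.61 (SE 0.11) and SRRM2 at 2.88 (SE 0.11). In HepG2 26 were higher and 24 lower, and camera did not call the list (adjusted p = 0.114). The snoRNA hosts of SNU-449 were higher in the nucleus in 19 of 24 cases and lower in 3 (camera adjusted p = 2.4e-04, adjusted p = 0.136 with an estimated correlation), though SNHG29 was at -3.01 (SE 0.11). In HepG2 13 hosts were higher and 6 lower, again with no call by camera (adjusted p = 0.173). G1 cyclins and their kinases were lower in the nucleus in 22 of 30 cases in HepG2 (camera adjusted p = 5.5e-04, adjusted p = 0.224 with an estimated correlation) and 20 of 28 in SNU-449 (camera adjusted p = 0.00186, adjusted p = 0.136 with an estimated correlation). CDK4 was at -3.05 (SE 0.14) and -3.62 (SE 0.10). Within the G2/M list of SNU-449, CENPF was at 4.48 (SE 0.12) and MAD2L1 at -3.62 (SE 0.11).

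The choice of the second 7-base word was revised after its results were seen. The first rule, itself written after a first look at the word scan, took the highest word of HepG2 that occurs in the C7orf25 mRNA and does not overlap the leading one. It gave TATTTAT, ranked 2 in HepG2 (coefficient 0.0992, z 9.20) and 6 in SNU-449 (0.0734, z 6.63). Other words of only A and T ranked high in HepG2 too, among them ATTTATT (rank 4, z 7.69), which is not in the C7orf25 mRNA. In shuffled draws with no effect added, the highest z in HepG2 was 5.135. The revised rule took the leading word of SNU-449 that does not overlap the first, GGAGAAA, ranked 8 in HepG2 (0.0794, z 6.89) and 2 in SNU-449 (0.1434). The counts of words given here use GGAGAAA. With TATTTAT in its place, 47.9% of the called rises in HepG2 and 59.8% in SNU-449 had neither word (62.3% and 60.5% of the searched genes), CDK6 held 4 matches, and 3.60% and 0.416% of the other genes with as many fell as far in the cytoplasm.

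The nucleus to cytoplasm ratio rose for part of the genes after siPANAD, and a candidate explanation is that the siRNAs act on other mRNAs through short matches in their 3' UTRs: GGTGCAA ranked 1 of 16384 words in HepG2 and had a coefficient of 0.23 in SNU-449 (0.2265, SE 0.0174), with a z of 13 against at most 5.92 among 419 rearrangements of its bases. It occurs in the C7orf25 coding sequence (42910792 to 42910798), as 15.4% of all words occur somewhere in that mRNA. The tables argue against matches to GGTGCAA and GGAGAAA in 3' UTRs as the source of every rise, since 56.7% of 764 rises in HepG2 and 63.5% of 1549 in SNU-449 had neither, against 73.0% and 72.2% of all searched genes (matches in coding sequence are not in these shares). They also argue against a bias acting alike anywhere in the mRNA (coding coefficient in SNU-449 of 0.155, SE 0.0177, against 0.2242, SE 0.0169, in the 3' UTR). Against fraction purity as the whole cause they argue only as far as the removed trend captures it. In the 15017 genes that this fit covers, 792 of 822 rises were called again in HepG2 and 1574 of 1624 in SNU-449. Of all shifts there, 91.0% and 88.9% were called again. The HepG2 count of 1722 shifts is 0.995 of the 1730 called among 17499 genes and 1.06 of the 1618 called among these. The bound also asked that the numbers of knockdown calls move, but in these genes they were 0.976 to 1.03 of those without removal. A purity difference that this stand-in misses is therefore not excluded. With the trend removed, 95.3% of the knockdown calls in those genes were made again in either HepG2 fraction, and 96.0% in cytoplasm but 82.5% in nucleus of SNU-449. A bias weaker in coding sequence stays open. So does whether the siRNAs carry these words, since their sequences are not given in the sources used here. A role of PANAD in export, which was not tested apart from the siRNAs, stays open too.

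For CDK6, retention in the nucleus with no other loss is argued against by the nuclear log2 fold change, which was below 0 in HepG2 (-0.56, SE 0.12) and SNU-449 (-0.80, SE 0.09). That value is relative to the typical nuclear gene, so a change shared by nearly all genes is not seen. Cytoplasmic RNA carried over into the nuclear fraction, in an unknown amount, would also lower it. The sign alone therefore does not exclude such retention. The CDK6 3' UTR of 10219 bases holds 1 GGTGCAA and 2 GGAGAAA. So long a 3' UTR has many places for such words, and GGAGAAA occurs in that of 2546 of 11264 searched genes in HepG2. Genes with 3 or more matches, which may hold GGAGAAA alone, did not shift more than genes with GGTGCAA only (medians of 0.11 and 0.18 in HepG2, 0.09 and 0.13 in SNU-449). Genes with both words, as CDK6 has, had median shifts of 0.16 in HepG2 and 0.14 in SNU-449. Their cytoplasmic medians were -0.36 and -0.29, against -0.31 and -0.24 with GGTGCAA only. Differences between these classes were not tested or adjusted for 3' UTR length. In so long a 3' UTR the matches are weak ground for a direct action of the siRNAs on CDK6, which is not excluded. Of the other genes with at least 3 such words, 3.63% fell as far in the cytoplasm in HepG2 (11 genes) and 1.23% in SNU-449 (4 genes), with medians of -0.28 and -0.29. The share of all searched genes that fell as far was not counted. A fall in transcription alone, at steady state, would lower both fractions alike. The higher ratio (log2 1.15 in HepG2 and 1.63 in SNU-449) argues against it as the only change. Retention together with another loss of CDK6 mRNA was not tested. Lower stability, or lower transcription with another change, through a loss of PANAD cannot be told apart from an action of the siRNAs on CDK6. The siRNAs were used as 1 mixture and their sequences are not given in the sources used here. The counts also neither show nor exclude a knockdown.

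C7orf25 had counts near 0 and its neighbour PSMA2 had few, and a candidate explanation is that reads shared with an overlapping gene on the same strand were left out of the counts. Among protein-coding genes with at least 50% of their exonic bases shared on their strand, as C7orf25 has (61.2%), 79.0% of 870 had a mean under 10 counts, against 38.0% of 11090 with none shared, a ratio of 2.08, and 46.0% of 137 with as much shared on the opposite strand. PSMA2 shares 14.6% of the bases of all its annotated exons and is not covered by that test. Those exons include a long one (42918074 to 42921931). Its exons at 42923325 to 42923406, 42924675 to 42924797 and 42926536 to 42926668 are also exons of ENSG00000256646. A PSMA2 mRNA without the long exon would therefore share more, by an amount that was not computed. Of 14 core proteasome subunits, PSMA2 (mean of 32.6 counts), PSMA6 (159.5) and PSMA1 (509.9) share bases on their strand and had the lowest counts, with the others between 1267 and 10907. Low expression stays open as a further reason, for C7orf25 and for other genes in such overlaps, so these counts neither show nor exclude a knockdown.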
